A study of Mus musculus with 4 samples.

How the data were processed

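Gene expression was measured in E14 cells, a line of mouse embryonic stem cells (ES cells), with 1-colour microarrays. Per the labels' protocols, the cells were transfected with a plasmid with lipofectamine, puromycin selection (1 mg/ml as the labels state it) began 1 day after transfection, and cells kept for 2 days in puromycin were harvested. RNA was extracted with Trizol, and Cy3-labelled cRNA was made from 1 ug of RNA with the Agilent Quick-Amp kit, per the labels' protocols. The 4 arrays carry 1 plasmid each: the empty pSuper vector, pSuper with a hairpin against luciferase, and pSuper with Mtf2 hairpin 1 or Mtf2 hairpin 3. The empty vector and the luciferase hairpin formed the control arm, and both Mtf2 hairpins formed the Mtf2 RNAi arm, 2 arrays in each. The design text speaks of 4 independent experiments, which leaves open whether a construct was repeated. Each construct has 1 array here, so p-values measure only the spread between these arrays, which includes differences between plasmids and may be technical.

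The values used are the deposited intensity of each array feature on a linear scale, with no log taken. The scanner, the feature extraction, the background method and the normalization are not given in the sources used here. Values at or below 0 (2260 to 2879 features per array, down to -1.8) show that a background had been subtracted. The deposited intensity had a median of 2.92 on the empty-vector array, 3.17 on the luciferase array and 3.22 on each Mtf2 RNAi array, and a maximum of 8308 to 11669. The medians differed by up to 0.14 log2, which is over the limit of 0.1 set in the design, so each array was scaled to a common 75th percentile of 22.98 units. Scaled values under 1 unit were raised to 1, and log2 was taken. The design did not foresee values at or below 0, so this floor was chosen after seeing the data. Of 45220 features, 10118 (22.4%) lay at the floor on all 4 arrays and were left out. At most 2879 features per array read 0 or below, so many of those left out had a positive value under the floor. The other 35102 were tested. For arrays, their number limits the precision, and no detection calls were used here.

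Features were named through the platform's annotation of 2016, which lists 33709 of them: 33653 carry 1 gene symbol, 56 carry several and were left unnamed, and 11511 features are not listed and stay unnamed. Of the listed features, 33517 have a gene identifier in a RefSeq gene table of the mouse assembly GRCm38.p6, and no symbol needed an update. Control spots could not be told from other unlisted features, and spots of 1 probe could not be averaged because no probe names were used. No coordinates are given, because no genome build is named for the values.

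Feature numbers were taken to run along 532 rows of 85 features. This was checked with the deviations of each feature from the median of the 4 arrays: features 85 numbers apart correlated with r = 0.40 on the empty-vector array and 0.22 to 0.24 on the others, against -0.03 to 0.05 for features 532 numbers apart. A position was called defective where the median deviation of its neighbours in a square of 7 by 7 features passed 0.5 log2 in either direction.

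The arms were compared with limma 3.58.1 (lmFit, then eBayes with an intensity trend) in R 4.3.3, with Benjamini-Hochberg adjustment over the 35102 features and a threshold of 0.05. The 24 gene lists, fixed in the design, were tested with camera at a preset inter-gene correlation of 0.01, with camera at an estimated correlation and with fry, on 1 feature per gene (16764 genes), and adjusted over the lists. A gene was represented by its brightest feature. Counts of features at least 1 log2 unit apart, and correlations between hairpins, carry no test. Differences are given as Mtf2 RNAi minus control in log2 units with the standard error (SE) of the limma fit.

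Named genes follow a rule fixed with the lists. Mtf2 comes first. Then come the 10 largest rises and 10 largest falls among features with adjusted p under 0.05, whose arms are separate and whose higher arm lies above the median feature. Places left open go to features with unadjusted p under 0.01 under the same conditions, as values without a call. Each list gives up to 4 members with the smallest p. For hairpin 3 against hairpin 1, and for luciferase RNAi against the empty vector, the 5 largest differences each way among features above the median level are named. Other features of a named gene are mentioned where they disagree in sign by over 0.5 log2. A few further members, and further features of a named gene, are given to describe a group and were chosen after their values were seen.

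The limma procedure was tested on simulated data with the spread of these arrays, over 35102 features. Changes were put only into features with a mean above 22.98 units. The noise was drawn independently, with no floor and no defective positions. The procedure called 2.35 unchanged features per run on average. It called 0% of features changed by 1 log2 unit, 0.6% of those changed by 2, 24.1% of those changed by 3 and 61% of those changed by 4. In separate runs over 16764 genes with 1 feature each, camera gave an unadjusted p under 0.05 for the PRC1 list, shifted by 1 log2 unit, in 20 of 20 runs. These simulated genes varied independently, and false calls were not counted. Smaller shifts and dimmer lists were not simulated.

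Alternatives chosen before the data were examined were quantile normalization, median centring, both eBayes settings, filters on dim features, a floor at the 25th percentile of each array (below 1 unit, so a lower floor), averaging the features of a gene, other thresholds, other set tests, exchanged controls and leaving out each array. Those chosen after seeing the data were no scaling, floors of 0.5 and 4 units, an offset of 5 units, features above the floor on every array, defective positions left out (alone, with the local trend subtracted, or with features averaged), and a fit over genes spotted at least 8 times. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.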

Results

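Transcript levels were compared between mouse E14 ES cells carrying an RNAi plasmid against Mtf2 and cells carrying a control plasmid, after 2 days of puromycin selection. Mtf2 is an accessory subunit of the Polycomb repressive complex PRC2, which places the repressive histone mark H3K27me3. The control arm held the empty pSuper vector and a hairpin against luciferase, and the Mtf2 RNAi arm held hairpins 1 and 3, with 1 array for each of the 4 plasmids. There are therefore no replicates of a plasmid, and the spread within an arm includes the difference between its plasmids. Across the 35102 features tested, log2 levels of the luciferase and both Mtf2 RNAi arrays correlated with Pearson r of 0.976 to 0.979. The empty-vector array correlated less with each of them (r of 0.945 to 0.949).

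The empty-vector array carried a region of low readings along 1 edge. Of its 45220 positions, 1668 were defective by the readings of their neighbours, against 6 on the luciferase array, 6 on the hairpin 1 array and 2 on the hairpin 3 array. Of the 1641 low positions among them, 1635 lay in columns 70 to 85 of the array. Among 11999 bright features, 460 read over 4-fold below the 4-array median on the empty-vector array, against 22, 16 and 36 on the others. Genes whose feature lies at such a position are named as such.

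**Figure D1:**
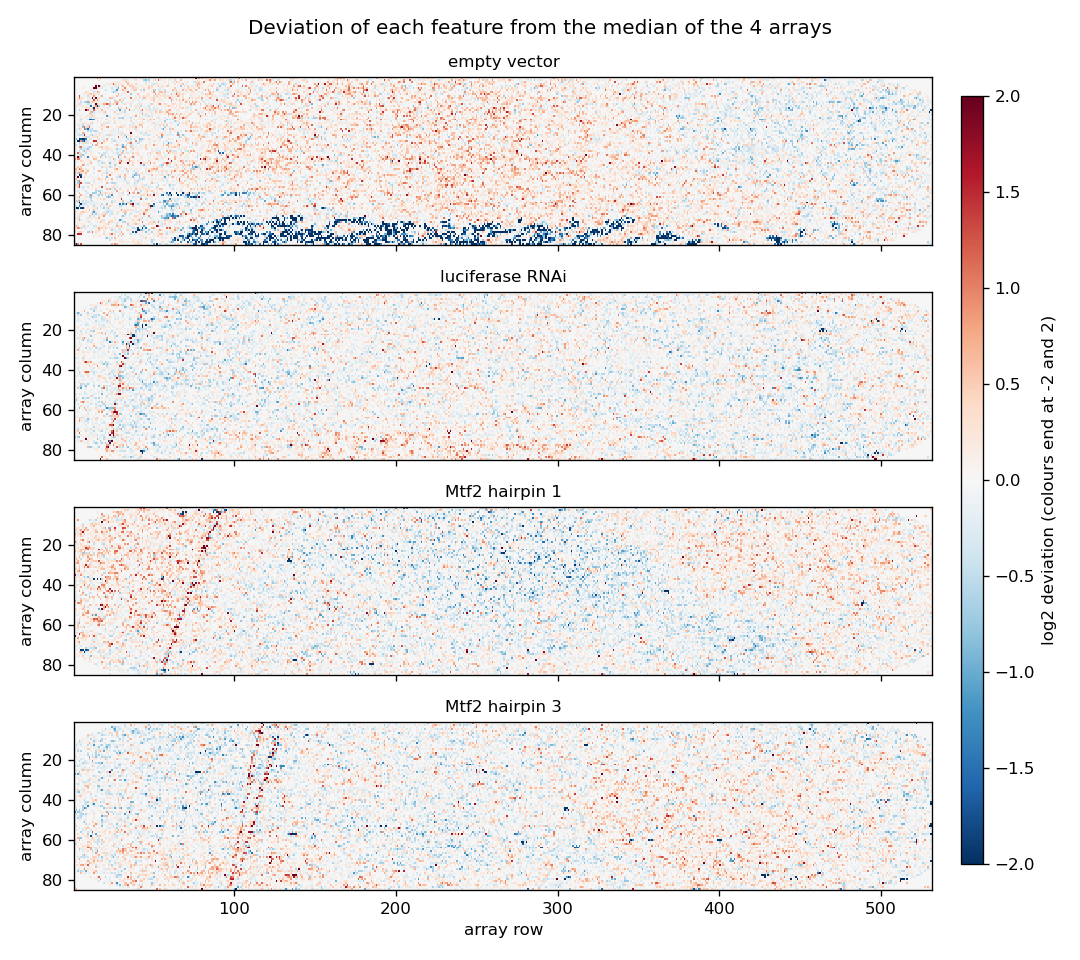
Map of each array by feature position, with the array row across and the array column downwards. Colour gives the log2 deviation of a feature from the median of the 4 arrays, from blue (lower) to red (higher), and ends at -2 and 2. The dark patch in columns 70 to 85 of the empty-vector array holds 1635 of its 1641 low positions, and a thin slanting line of raised features crosses the other 3 arrays.

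Mtf2 itself was the target and was examined first, on 4 features. On 3 of them both Mtf2 RNAi arrays read below both control arrays. Feature 23720 read -1.08 log2 (SE 0.21), which leaves 0.474 of the control level. Feature 23882 read -1.03 (SE 0.32, 0.492 of control), at -1.42 with hairpin 1 and -0.63 with hairpin 3. Feature 2472 read -0.78 (SE 0.22, 0.583 of control). Scaled intensities on feature 23720 were 215.8 with the empty vector, 243 with the luciferase hairpin, 105.2 with Mtf2 hairpin 1 and 112 with Mtf2 hairpin 3. The brightest feature, number 321, which represents the gene by rule, went the other way, at +0.19 log2 (SE 0.71). Its intensities were 174.8 with the empty vector, 737.2 with the luciferase hairpin, 501.1 with hairpin 1 and 335 with hairpin 3, with the empty vector lowest. Its difference was -0.85 without that array, 1.23 without the luciferase hairpin, -0.10 without hairpin 1 and 0.48 without hairpin 3. The mean of the 4 features was -0.67 (SE 0.27), or 0.627 of control, at -0.71 with hairpin 1 and -0.64 with hairpin 3. None of these differences passed limma's test over all features. The adjusted p was 0.868 for each of the 3 lower features, 0.954 for feature 321 and 0.881 for the mean.

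**Figure D2:**
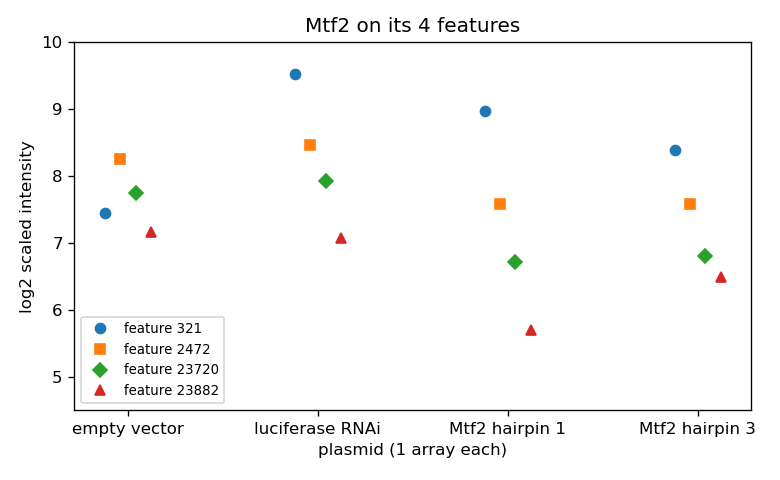
Level of Mtf2 on each array, as log2 scaled intensity on the vertical axis, with the 4 plasmids along the horizontal axis and 1 marker shape for each of the 4 Mtf2 features. On features 2472, 23720 and 23882 both Mtf2 hairpins lie below both controls, by -0.78, -1.08 and -1.03 log2 on average, while feature 321 is lowest with the empty vector.

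The main comparison asked which transcripts differ when Mtf2 is targeted. No feature passed the threshold (0 of 35102, limma, smallest adjusted p = 0.868). An unadjusted p under 0.05 was reached by 1467 features, 568 higher and 899 lower with Mtf2 RNAi, against 1755 expected by chance. The other ways to pair the arrays gave fewer, 942 and 1112. Leaving out the empty vector, luciferase or hairpin 3 array raised the count above that expected by chance, and leaving out hairpin 1 did not. An arm of 1 array has no spread of its own, so these counts are no sign of an Mtf2 effect. Without the luciferase array, the control arm is the empty-vector array with its low edge, whose deviations enter the difference. Since no feature passed, the genes below are given as values without a call, all at a limma adjusted p = 0.868. The simulation changed only features above 22.98 units. It called none of those changed by 1 log2 unit and 0.6% of those changed by 2. For single features of that brightness, 2 arrays against 2 thus could not resolve changes of that size. Changes in dimmer features were not simulated.

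Among the features with unadjusted p under 0.01, separate arms and a level above the median feature, the highest value with Mtf2 RNAi was that of Ndufb8, a subunit of mitochondrial complex I (5.02-fold, 2.33 log2, SE 0.57). Its controls were far apart, at 115.2 with the empty vector and 362.9 with the luciferase hairpin, against 951.1 and 1110 with the Mtf2 hairpins, and it lies in column 76. Its difference was 1.501 log2 without the empty vector and 3.157 without the luciferase hairpin. The condensin II subunit Ncapg2 read 1.40 log2 higher (SE 0.23), at 63.66 and 52.79 in the controls and 142.4 and 164.8 with the Mtf2 hairpins. The Mediator subunit Med16 read 1.34 higher (SE 0.25), and its other feature 0.75 higher. The scaffold gene Tanc1 read 1.21 higher (SE 0.24), while its other features read -0.001 and 0.26. Commd1, a regulator of copper handling and NF-kB, read 1.19 higher (SE 0.25), with 0.10 and 2.04 on its other features. The 2.04 rests on the empty-vector array, which was at the floor in column 85. Cytoskeletal actin, Actb, read 1.19 higher (SE 0.27) on its brightest feature, and its other 9 features were all higher too, from 0.59 to 1.22. Dim genes in this group were the heat shock factor Hsf4 (1.47, SE 0.31), the Notch pathway repressor Hey2 (1.24, SE 0.30) and 4930544G11Rik (1.42, SE 0.33). Zbtb9 (1.75, SE 0.35) was at or near the floor in both controls and lies at a defective position of the empty-vector array.

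Of the 10 lowest values under the same conditions, that of Ascc2, a subunit of the activating signal cointegrator complex, was the only one from a feature above 10 scaled units. It read -1.92 log2 (SE 0.33), at 198.8 and 131.3 in the controls against 52.17 and 34.82 with the Mtf2 hairpins, but its other feature read -0.01. The remaining 9 genes stood below 10 scaled units on every array. Tmem255a read -2.03 (SE 0.49), with -0.54 on its other feature. It was at the floor with hairpin 1, so the size of its difference depends on the floor. Tph1, the tryptophan hydroxylase of serotonin synthesis, was at the floor with both Mtf2 hairpins and thus at least 3.30-fold lower than the controls. The sperm surface gene Adam3 read -1.71 (SE 0.37). Zfyve9, an adaptor for Smad proteins, read -1.69 (SE 0.39), while 1 of its other features was 0.63 higher. The pseudogene Vmn1r-ps103 (-1.60, SE 0.28), 9530053A07Rik (-1.59, SE 0.28), the T cell adaptor gene Sla2 (-1.55, SE 0.36), the melanosome receptor gene Gpr143 (-1.49, SE 0.34) and E130112N10Rik (-1.48, SE 0.33) complete the group. Gpr143 and E130112N10Rik were also at the floor with hairpin 1, so the sizes of their differences depend on the floor.

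The Hox genes, which pattern the body axis and are classical Polycomb targets, were the only 1 of 24 lists to pass. Of 31 measured members, 23 were higher and 8 lower with Mtf2 RNAi, with a median of 0.29 log2 and a mean of 0.25 (camera with a preset correlation, adjusted p = 0.0444). With an estimated correlation the adjusted p was 0.987, and with fry it was 0.559. The estimated correlation was 0.017, close to the preset 0.01, while the unadjusted camera p went from 0.00185 to 0.103. A preset correlation makes camera take genes as its replicates, whereas an estimated one ties the test to the few arrays. The call at 0.0444 thus does not carry the uncertainty of so few arrays. Arms were separate for 11 members in the higher direction and 2 in the lower. Hoxb7 read 0.81 higher (SE 0.32), Hoxa7 0.76 (SE 0.34), Hoxd9 0.84 (SE 0.39) and Hoxb6 0.61 (SE 0.29), and among the lower members Hoxb13 read -0.51 and Hoxb9 -0.50. These are dim features, 18 of the 31 at or below the median feature level. The call was lost without the empty-vector array (adjusted p = 0.146), without the luciferase array (0.361) and without hairpin 3 (0.737), and held without hairpin 1 (0.00823). No member of this or any other list passed alone, over all features or adjusted over the list alone (0 members in each of the 24 lists).

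Cholesterol synthesis genes were the next list. Of 18 members 14 were lower, 9 of them with separate arms, and the median was -0.22 log2, which did not pass (camera, adjusted p = 0.0944). Insig1, the sterol sensor partner, read -0.72 (SE 0.31), squalene synthase Fdft1 -0.56 (SE 0.25), Pmvk -0.57 (SE 0.28) and Hsd17b7 -0.60 (SE 0.30). The other 22 lists had camera adjusted p of 0.724 or above.

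Among Polycomb genes, 5 of 12 PRC2 members besides Mtf2 were higher and 7 lower, with a median of -0.16. Jarid2, which helps to recruit PRC2, read 0.84 higher (SE 0.29), and Epop 0.62 higher (SE 0.33). The core subunits Suz12 and Eed read -0.59 (SE 0.24) and -0.70 (SE 0.35), and the catalytic subunit Ezh2 0.24 higher (SE 0.44). The 20 PRC1 members centred on -0.03, with Bmi1 0.45 higher, Cbx8 0.50 higher, Phc3 at -0.42 and Cbx6 at -0.29.

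Genes of general and naive pluripotency split into 18 higher and 13 lower (median 0.09). Klf4 read 1.02 higher (SE 0.40) and Tbx3 0.94 higher (SE 0.35), while Tet2 read -0.74 (SE 0.30) and Nr5a2 -0.63 (SE 0.28). The core factors Pou5f1 and Sox2 each read 0.22 higher, within 1 SE of 0 (SE 0.27 and 0.28). Primed epiblast genes split 7 and 7 (median -0.04), with Krt19 at -0.53, Foxd3 0.64 higher, Fgf15 0.63 higher and Sox3 at -0.85. The 2-cell-like state list had 7 of 12 members higher (median 0.12), with Sp110 0.76 and Tcstv1 0.56 higher, Tdpoz1 at -0.63 and Usp17lc at -0.43.

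None of the lineage marker lists passed. For genes spotted at least 8 times, the difference of the median over spots is given beside that of the brightest feature, a comparison added after seeing the data. Primitive streak and mesoderm genes had 12 higher and 14 lower (median -0.06), with Snai1 at -0.72, Fgf8 at -0.68 (-0.25 over its 10 spots), Pdgfra at -0.84 and Twist1 1.89 higher (SE 1.00), the last with the empty-vector array near the floor and apart from the other 3. Over its 11 spots Pdgfra read +0.20, within 1 SE of 0 (SE 0.22), with 6 spots higher. Endoderm genes had 15 higher and 11 lower (median 0.06), with the laminin chain Lamc1 at -1.05 (SE 0.37), Rbp4 at -0.66, Gata4 at -1.27 and Thbd 0.57 higher. Neuroectoderm and neuron genes had 15 higher and 9 lower (median 0.10), with Neurog1 0.89 and En2 0.75 higher, and Ncam1 at -0.82 and Tubb3 at -0.64. Over repeat spots En2 read 0.52 higher, Ncam1 -0.02 and Tubb3 -0.14. Trophoblast genes had 10 higher and 5 lower (median 0.05), with Gata3 0.76 and Cdx2 0.32 higher, Fgfr2 at -0.84 and Tfap2c at -0.37. Markers of fibroblasts and feeder cells, another cell type an ES cell culture can hold, had 6 higher and 11 lower (median -0.09). Among them Ccn2 was 1.52 higher (SE 0.67), Thy1 read -0.43, Col1a1 -0.52 and Col1a2 -0.47, while Col1a1 read 0.03 over its 12 spots.

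Germline genes silenced in ES cells split 8 higher and 11 lower (median -0.05), with Stra8, the retinoic acid response gene of meiosis, at -0.91 (SE 0.26), Asz1 at -0.86, Taf7l at 0.58 and Sycp3 at 0.48. Imprinted genes split 14 and 12 (median 0.07). The imprinted RNA H19 read -0.88 (SE 0.30), Mirg -0.56 and Phlda2 0.74 higher, and Grb10 read 4.54 higher (SE 1.94), with the empty vector at the floor at a defective position. Histone genes had 8 higher and 4 lower (median 0.04), with H3f3a 0.56 higher, H4c1 at -0.31, H2bc21 at -0.41 and H3f3b 0.28 higher.

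The growth and stress lists did not pass either. Proliferation genes had 16 higher and 14 lower (median 0.02), with Birc5 and Ccne1 each 0.84 higher, Myc at -0.70 and Ccnd1 at -0.51. Over repeat spots Myc read -0.47, and Ccnd1 +0.11, within 1 SE of 0 (SE 0.15), with 6 of 10 spots higher. Cell cycle inhibitors had 6 higher and 7 lower (median -0.05). Cdkn2a, the Ink4a/Arf gene and a textbook Polycomb target, read 0.93 higher (SE 0.32), Cdkn1c 0.70 and Rbl2 0.56 higher, and Gadd45b -0.72. The p53 response had 11 higher and 9 lower (median 0.01), with Eda2r 1.11 and Btg2 0.86 higher, and Perp at -0.83 and Fas at -0.89 (-0.48 over its 10 spots). The unfolded protein and amino acid stress list had 15 higher and 11 lower (median 0.04), with Trib3 0.95 higher (SE 0.30), Xbp1 0.85, Atf5 0.52 and Slc3a2 1.31 higher, the last at a defective position. Hypoxia and glycolysis genes had 10 higher and 16 lower (median -0.12), with Ldha 0.85 higher, Hk2 at -0.53, Aldoc at -0.70 and Ankrd37 at -0.38. Targets of Nodal, BMP and Wnt signalling had 6 higher and 10 lower (median -0.03), with Skil at -0.92 (at a defective position), Dkk1 at -0.69, Smad6 at -0.69 and Sp5 at -0.51.

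Lists that bear on the RNAi procedure, and housekeeping genes, did not pass. The interferon and double-stranded RNA response had 9 higher and 14 lower (median -0.05), with Stat2 0.50 higher, Zbp1 at -0.85, Mx1 at -0.65 and Oas3 at -0.44. Small RNA machinery had 10 higher and 5 lower (median 0.02), with the precursor exporter Xpo5 at -0.83 (SE 0.29), Dgcr8 0.69 higher, Prkra at -0.51 and Tnrc6c at -0.71. Housekeeping genes had 5 higher and 9 lower (median -0.13), with Actb as above, Gusb at -0.80 (SE 0.26), Sdha at -0.39 and Rplp0 0.64 higher. Over repeat spots Gusb read only -0.05, with 6 of 10 spots higher, and Rplp0 0.24. In 9 of the 24 lists the median and the mean differed in sign, among them the PRC2, PRC1, mesoderm, endoderm and cell cycle inhibitor lists.

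**Figure D3:**
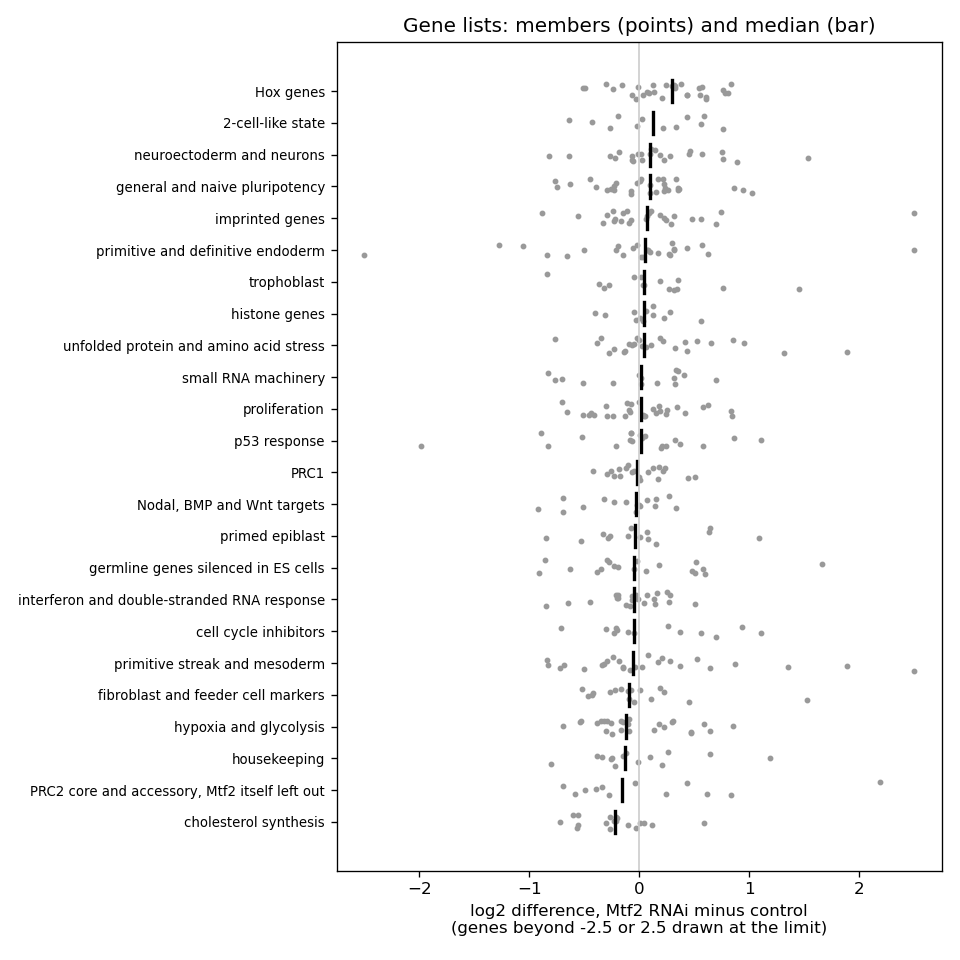
Difference between Mtf2 RNAi and control in log2 units on the horizontal axis for each measured member (grey point) of the 24 gene lists, with the list's median as a black bar. The Hox genes have the highest median (0.29) and cholesterol synthesis the lowest (-0.22), and 4 members beyond the axis are drawn at its ends.

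A rule of size that needs no variance model gave a small excess for the real arms. In 122 features both Mtf2 RNAi arrays lay at least 1 log2 unit from both control arrays on the same side, 49 higher and 73 lower. The other ways to pair the arrays gave 75 and 57. At sound positions the counts were 110 against 61 and 46. At 0.5 log2 the real arms gave 1314 features, against 946 and 1112. No test was run on these counts, since 4 arrays allow only 3 such pairings.

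Whether both hairpins moved the same features was examined with disjoint controls. Across the 35102 features, hairpin 1 minus the empty vector and hairpin 3 minus the luciferase hairpin correlated with Pearson r = 0.0139 (Spearman 0.0369). With the controls exchanged the values were 0.0156 and 0.0573. Features are not independent replicates, so these values carry no p. Above the median level and at sound positions, r was 0.0346 and 0.0414. Taking each hairpin against the mean of both controls gave r = 0.525 and a covariance of 0.207, but unchanged samples simulated against shared controls gave 0.517 and 0.200.

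Both hairpins target Mtf2, so their difference shows the spread within the arm. Hairpin 3 and hairpin 1 differed at least 2-fold on 2773 features (7.90%), 1402 higher and 1371 lower with hairpin 3. Nearly all extremes were differences of 1 array from the other 3. With hairpin 3, the homeobox gene Meis1 read 182.6 against 1.74 with hairpin 1 and 1.70 and 1.08 in the controls, and the membrane anchor gene Prima1 194.7 against 1.88. With hairpin 1, Zfp516 and keratin gene Krt18 read 1.99 and 8.73 against 76.84 and 293.7 with hairpin 3. Ate1 differed from the rest: it read 1.48 with hairpin 1 and 60.95 with hairpin 3, below and above the controls (5.64 and 8.99). These 3 genes lie at defective positions of the empty-vector array, not of the hairpin arrays. In the other direction, the ribosomal protein gene Rpl30 read 3.94 with hairpin 3 against 2566 with hairpin 1, and the redox sensor gene Park7 7.18 against 981.5. Dlgap4 read 1.16 against 131.7, and Mast2 and Dhps were at the floor with hairpin 3, at least 7.12 and 6.97 log2 lower than with hairpin 1. Other features of these genes did not share the difference: Rpl30 differed by -9.35 log2 on its brightest feature and -0.03 on the other, and Dlgap4 by -6.82 against a mean of 0.74. For Zfp516 the values were 5.27 against 0.36, and for Ate1 5.36 against -0.10.

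The luciferase hairpin was compared with the empty vector as the background for single-array differences. They differed at least 2-fold on 3496 features (9.96%), 2041 higher and 1455 lower with the luciferase hairpin. Above the median level, the count fell from 2182 features to 1591 when defective positions were left out, and the higher ones from 1445 to 856. The largest values with the luciferase hairpin came from the low edge of the empty-vector array: the proteasome gene Psmd11 (1897 against 1.505), the ribosomal protein gene Rps16 (4164 against 4.64), Cdk5r2 (735 against 1.18) and the actin-nucleating gene Arpc1b lie at defective positions. The complex I gene Ndufb10 lies in column 72 and was at the floor with the empty vector, as was Arpc1b, so they were at least 10.10 and 9.28 log2 higher with the luciferase hairpin. The lowest values with the luciferase hairpin were again mostly its own. The autophagy receptor gene Nbr1 read 5.29 against 333.3, Rbm38 1.19 against 14.03, Cntnap1 2.18 against 22.49, and the vitamin transporter gene Slc5a6 was at the floor, at least 4.86 log2 lower. Rtn4 read 28.59 against 295.6, and there the Mtf2 hairpins (48.81 and 36.52) resembled the luciferase array. Nbr1 differed by -5.98 log2 on its brightest feature and by a mean of -0.04 on its others. Cntnap1 went the other way on its other feature, which is dim (-3.36 against +1.26 log2).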

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

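No feature passed an adjusted p of 0.05 under any alternative run over all features, so that count stayed at 0. The added fit over 158 genes with repeat spots called 3 genes, and 7 without scaling. Raising the limit to 0.1 or adding a 1 log2 limit also left 0. Scaling to the 75th percentile, listed beforehand among the alternatives, is the setting reported. Settings named here as added were chosen after seeing the data. With an arm reduced to 1 array, that array is assumed to vary like the others. No paired analysis was possible because the labels number only the hairpins, and nothing ties a control plasmid to either of them. For Mtf2 (main value 0.19 log2 on the brightest feature) averaging its features gave -0.67, also with defective positions left out (added). Leaving out each array gave -0.85 without the empty vector, 1.23 without the luciferase hairpin, -0.10 without hairpin 1 and 0.48 without hairpin 3. The other 3 features stayed lower under every setting that kept features apart. The count of gene lists past the threshold (1) became 0 with an estimated correlation, fry, the 25% and 50% dim-feature filters, the 25th percentile floor, and, added, a floor of 0.5 unit, the local trend subtracted and an offset of 5 units; it was 0 to 1 with each array left out. The cause was not tested.

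The 122 features 2-fold apart in every pairing became 1314 at 0.5 log2, 21 without the dimmest 50%, 188 with the 25th percentile floor and 39 with features averaged. Added settings gave 281 (floor 0.5), 27 (floor 4), 68 (above the floor on every array), 79 (local trend subtracted), 36 (defects left out, features averaged) and 14 (offset 5). Luciferase against empty vector (3496) became 1479 without the dimmest 50% and 1484 averaged. Added settings, in the same order, gave 5370, 1762, 2226, 2282, 1058 and 1393. Hairpin 3 against hairpin 1 (2773) became 890 and 944, and, added, 4805 (floor 0.5), 1078 (floor 4), 946 (defects left out, averaged) and 591 (offset 5). Hairpin agreement (r = 0.0139) became 0.0156 with controls exchanged and 0.0088 without the dimmest 50%. Added settings gave 0.0160 (floor 4), 0.0230 (above the floor), 0.0342 (defects left out), 0.0359 (local trend) and 0.0363 (defects left out, averaged). There were 448 other values for single genes, the Hox list and counts at unadjusted p. Of these, 432 were classed as the same, 14 as weaker and 2 as stronger, and none changed sign. The genes named as largest rises and falls were chosen for separate arms. Leaving out 1 array could not change their sign, so this count is no support for them. The count of features with unadjusted p under 0.05 (1467) rose whichever array was left out, where the reduced arm of 1 array has no spread of its own. Values near the floor are limited by the signal over background.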

Other observations

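The fit over repeat spots, the tests of the low edge, the Hox level-matched and leave-one-out tests, and the Actb spot and brightness tests were chosen after the results were seen. The tests on the other developmental families and on the actin genes were written before their values were computed.

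Some genes were spotted many times on this array, which averages out the error of single features. Of 217 genes with at least 8 features of 1 accession, 158 stood above the floor on all 4 arrays. Genes were counted here by symbol and accession, so Egfr entered with 2 accessions, at -0.71 and +0.13 log2. Taking the median over spots and fitting limma to these 158 genes alone, 3 passed, all higher with Mtf2 RNAi. Without scaling between arrays 7 passed, 3 higher (Actb, Cdkn2a, En2) and 4 lower (Fos, Myc, Mitf, Cdkn1a), and with median centring or quantile normalization 2 (Actb and Pgk1). Cdkn2a, which encodes the cell cycle inhibitors p16Ink4a and p19Arf and is a textbook Polycomb target, was 1.08 log2 higher (2.11-fold, SE 0.21, adjusted p = 0.000891), on 10 of 10 spots. Actb was 1.05 higher (2.07-fold, SE 0.15, adjusted p = 2.81e-05), and the glycolytic gene Pgk1 0.35 higher (SE 0.05, adjusted p = 2.81e-05), on 6 of 11 spots, while its brightest feature read -0.26. Without the luciferase array Cdkn2a was 0.65 higher (1.57-fold, adjusted p = 0.0634), and without the empty vector 1.51 higher (2.84-fold). The adjusted p of Pgk1 was 0.0776 without the luciferase array, and without the empty vector it was 0.0584. Median centring and quantile normalization gave 0.0516 and 0.105 for Cdkn2a, with differences of 1.02 and 1.06, and no scaling gave 0.0617 for Pgk1. Cdkn2a is dim on these arrays, at 1.44 to 3.14 log2 units. It read 2.30 with the empty vector and 1.44 with the luciferase hairpin, so its controls lay further apart than its SE. Limma moderates each gene's SE with the spread of the other genes in the fit. The SE and adjusted p of single genes here, Pgk1 included, thus lean on the panel and not only on their own 4 arrays. The other ways to pair the arrays gave 0 genes each.

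Genes short of the threshold in the scaled fit included the homeobox gene En2, 0.52 higher on 10 of 10 spots (adjusted p = 0.0517), and Mitf at -0.60 (0.0517). The immediate early gene Fos read -0.55 (adjusted p = 0.0527; -0.72 without the empty vector, -0.37 without the luciferase array), Myc -0.47 (0.0793) and Fas -0.48 (0.0878). Cdkn1a, the main p53 target among the inhibitors, read -0.49 and was lower on all 10 spots (adjusted p = 0.104). The empty-vector array carried most of this: without it the difference was -0.165 (adjusted p = 0.919), and without the luciferase array -0.82 (adjusted p = 0.000348). Across the 158 genes both hairpins correlated more than across all features. Pearson r with disjoint controls was 0.39 and 0.35 (Spearman 0.285 and 0.206), and Pearson r was 0.34 and 0.30 without Actb. The panel holds medians over at least 8 spots, above the floor on all arrays, so the comparison differs in noise as well as in genes. In a single simulated run of these 158 genes, 20 of 20 genes changed by 1 log2 unit were called, with 1 false call. Every simulated gene had the same spread, whereas the SE in the real fit was 0.05 for Pgk1 and 0.21 for the dim Cdkn2a. How often a change in dim genes would be called was therefore not tested.

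The 1st pattern is the low edge of the empty-vector array. In 27 genes with repeat spots, 30 spots lay at its low positions, and there they read -4.72 log2 below the same genes' spots at sound positions of that array. The same spots on the luciferase, hairpin 1 and hairpin 3 arrays differed by -0.01, -0.07 and 0.12. A difference between the plasmids would leave repeat spots of 1 gene alike on the empty-vector array, so it is argued against, and a local defect of that array's surface is the candidate explanation that remains. What produced it was not tested.

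The 2nd pattern is the higher median of the Hox list. It lay above 99.99% of 10000 lists of the same size and level, which argues against a general shift of dim features. The median stayed at 0.20 log2 or above whichever array was left out. Without hairpin 3, 17 members were higher and 11 lower, against 23 and 8 with all arrays. No level-matched lists were drawn with an array left out, so whether 1 array carried the pattern was not settled. A candidate explanation is release of developmental transcription factor genes at large. The 101 genes of other homeobox, T-box, Fox, Gata and bHLH families had a median of 0.07, above 92.9% of level-matched lists. By the prediction written beforehand, a value at or below 95% counted against this explanation. The median plus 1 bootstrap SE (0.048) passed the 95th percentile of those lists (0.072), a further rule not in that prediction. The test was therefore taken as undecided. Paired as luciferase and hairpin 3 minus the other arrays, the Hox median was 0.07, above 92.78% of level-matched lists. Paired as luciferase and hairpin 1 minus the others, it was -0.12, above 19.99%. With 3 pairings of 4 arrays, a difference between plasmids other than Mtf2 loss stays open.

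The 3rd pattern is Actb. Its median over spots was 4.673 log2 units with the empty vector, 4.987 with the luciferase hairpin, 5.795 with hairpin 1 and 5.964 with hairpin 3. All 10 of its spots were higher with Mtf2 RNAi, which argues against error of single spots, and without any scaling between arrays Actb was 1.07 higher while the other genes with repeat spots had a median of -0.021, which argues against brightness of whole arrays. A shift of the size of Actb's in the genes of SRF and the actin cytoskeleton at large is argued against too: 33 of them, 15 higher, had a median of -0.06 (bootstrap SE 0.07), above 15.4% of level-matched lists. Whether all 10 spots carry the same probe is not known here, so a property of that probe stays open too. How fully these spots report Actb mRNA was not tested. A change of Actb that the genes of SRF and the actin cytoskeleton do not share stays open as a hypothesis and was not tested.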
